A study of Homo sapiens with 2 samples.

How the data were processed

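RNA of PLC5 cells was measured on 2 arrays, 1 from cells transduced with a lentivirus carrying a non-targeting shRNA and 1 from cells transduced with a lentivirus carrying an shRNA against CTCF. The groups come from the sample descriptions; the title of the second sample calls the construct an siRNA. Per the labels' protocols, cells were transduced for 24 h, kept in puromycin for 24 h and returned to normal medium for 48 h before RNA was collected, and 0.5 ug of RNA was labelled with Cy3. The labels do not mention spike-in RNA.

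The deposited scanner files hold intensities on a linear scale, made with Agilent Feature Extraction per the file headers, from arrays of Agilent design 014850 scanned at 5 micron. The headers give release 11.0.1.1 and the submitters' processing notes give 11.1. The processed signal is background-subtracted and spatially detrended, per the file headers, with a positive substitute value for dim spots, and it is not scaled between arrays. The deposited value table of the series holds the same intensity values, rounded, with a largest difference of 0.497% from the processed signal and column medians of 19.8 and 56.0. It is linear and not centred, and it was used as an alternative.

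Log2 of the processed signal was taken for non-control spots, and the 75th percentile of each array was subtracted. The 3310 spots marked as non-uniform or as population outliers on either array were left out. Spots of 1 probe were averaged, and a gene with several probes was represented by the probe of highest mean signal over both arrays. A gene was counted where that probe was well above background on at least 1 array. Where it was seen on 1 array only, the difference is a bound against the higher of the dim probe's own signal and the lowest signal well above background on that array, written as at least N-fold. Where the dim probe's own signal was the higher, the value is the measured difference and is given as measured. The scanner files used here pair probes with accessions and not with gene symbols, so symbols were taken by matching accessions without versions to a RefSeq gene table (GRCh38.p14), which replaced the planned use of a symbol column. Of 41000 probes, 27288 matched 1 symbol, 0 matched several and 13712 matched none and are not named here. They cover 18228 genes, of which 17321 had a usable spot.

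With 1 array per group there was no test across samples, and no p-value is given. Sizes are set beside the scanner's error estimate, the SD between spots of probes printed 10 times (189 of 264 such probes had at least 5 usable spots) and the agreement of a gene's probes, which describe the arrays and not variation between cultures. The number of arrays limits the precision. Gene lists (31, of which 30 had at least 3 counted genes) were fixed before the data were examined, as were the size threshold of 2-fold, the rule for named genes and the alternatives listed next, except where stated. For each list, the median difference was placed among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. The rule named the 12 highest and 12 lowest genes seen on both arrays that kept their sign and a log2 size of at least 1 under a second normalization, the 5 largest bounds per direction, up to 4 members of each list with the largest differences, and CTCF, CTCFL, FOXM1, MYC, TERT, IGF2 and H19. Open reading frame names and clone names were left out. The results of 1 gene and the summaries of 2 lists are not reported here. Further list members named in the text were chosen after their values were seen.

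The alternatives were normexp background correction (offset 50) with quantile normalization, scaling on the median of all probes, on the reference genes or on probes seen on both arrays, cyclic loess (3 iterations), the deposited value table, other filters on dim probes, the median over a gene's probes, outlier spots kept, and thresholds of 1.5-fold and 3-fold. Normexp was run on median spot and background intensities, because the files used here hold no mean signal column. Both arrays lie on 1 slide and no spot was saturated, so slide and saturation were not varied. Another 3 alternatives were added after the data were examined. They used measured values in place of bounds, kept only genes brighter on at least 1 array than the brightest E1A or eQC control probe, which a rise can itself bring about, and left out 28 genes whose probes were at least 2-fold apart in opposite directions.

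The gene table was tested on simulated data made from the non-targeting array's signals and scanner errors, standing for the CTCF shRNA minus non-targeting comparison over 12667 genes. All 50 genes simulated at a log2 difference of 2 and all 50 at -2 passed 2-fold, as did 100% of those at 1.5 and 98% of those at -1.5. Of 12437 unchanged genes, 0.153% passed. A list of 30 genes shifted by 0.8 gave a median of 0.80 at percentile 100, and an unshifted list lay at percentile 87.3. The simulated arrays shared the detection calls and flags of the non-targeting array and differed by scanner noise alone. The changed genes were drawn from those seen on both real arrays, without the dimmest. These shares therefore check the steps and give no error rate for the real comparison. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.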

Results

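Gene expression was measured in PLC5 cells, a human hepatocellular carcinoma line, after lentiviral delivery of a short hairpin RNA (shRNA) against CTCF or of a non-targeting shRNA. CTCF is a zinc finger protein that binds insulators and helps to shape chromatin loops. Each group held 1 array, so no difference has a replicate check and none was tested across samples. The arrays were 1-colour Cy3 Agilent arrays hybridised on 1 slide, each with 45015 spots and 41000 distinct probes outside the control probes. The 75th percentile of the processed signal was 268 intensity units on the non-targeting array and 377 on the CTCF shRNA array. A share of 59.3% of the 43376 non-control spots was well above background on the non-targeting array and 64.8% on the CTCF shRNA array. Feature Extraction marked 1 spot as non-uniform on the non-targeting array and 3247 spots, or 7.21%, on the CTCF shRNA array. No spot was saturated on either array. Differences are given as CTCF shRNA minus non-targeting shRNA on the log2 scale, or as the larger over the smaller normalized signal. A gene is called seen where its probe was well above background.

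The comparison set liver cancer cells given the CTCF shRNA against cells given the non-targeting shRNA, and CTCF was seen on both arrays. CTCF itself read lower with its shRNA, by a log2 difference of -0.70 with a scanner error of 0.24, or 61.6% of the control level. The size depended on the scaling, and with scaling on reference genes the difference was -0.13, within that error. H19, the imprinted RNA next to IGF2, had a log2 difference of -7.03 (-5.28 after normexp background correction and quantile normalization), and FOXM1, a transcription factor of mitotic entry, was 3.01-fold lower. Hepatocyte genes were lower as a group, led by AHSG at 73.5-fold and APOC3 at 43.7-fold, and so were hypoxia and glycolysis genes such as ANKRD37. Heat shock chaperones such as HSPH1 and antioxidant genes such as HMOX1 were higher as groups. The chemokine gene CXCL1 and the vasoconstrictor peptide gene EDN1 were higher by 3.50 and 4.59 on the log2 scale, and by 3.59 and 4.01 after normexp and quantile normalization.

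The knockdown itself was measured by 2 CTCF probes. The brighter probe read 68.5 intensity units with the non-targeting shRNA and 59.3 with the CTCF shRNA, against array percentiles that went the other way. The dimmer probe, at 12 and 9.78 units, gave -0.78 with a scanner error of 0.77 and was not well above background on the CTCF shRNA array. Both probes lay below the brightest control probe without a human target on that array, which read 131 units. A log2 difference at or below that of CTCF was found for 2778 genes, or 20.9% of those counted. The CTCF difference was -0.13, within its scanner error, when the arrays were scaled on reference genes and -1.58 when they were scaled on the median of all probes. CTCFL, the germline paralog of CTCF, and IGF2 were not well above background on either array.

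Among genes that reports elsewhere place under CTCF control, the kinase gene PIM1 was 4.77-fold lower, besides H19 and FOXM1. H19 read 2938 units in the control and 31.5 with CTCF shRNA, the latter below the brightest control probe. MYC was higher by 0.91 (SD 0.07 over 9 spots) and TERT, the catalytic subunit of telomerase, by 0.39 (SD 0.12 over 9 spots), which is 0.85 and 0.33 above the median of all genes. Cohesin and other loop factors were close to the remaining genes, with a median of -0.16 over 13 genes, at percentile 30.5 of random lists matched on mean signal. The cohesin regulators PDS5B and WAPL were 2.40-fold and 2.12-fold higher at their main probes. The other 2 probes of PDS5B differed by 0.63 and 0.63, and the second probe of WAPL by 1.52. ZNF143, which reports elsewhere place with CTCF at loop anchors, differed by -0.77. Imprinted genes had a median of -0.35 over 19 genes (percentile 6.06), with 4 at least 2-fold higher and 7 lower. PHLDA2 was 6.50-fold higher and L3MBTL1 3.61-fold lower. DLX5 was at least 4.01-fold higher, at a signal below the brightest control probe. After an intensity-dependent normalization by cyclic loess the imprinted list lay at percentile 0.60, below the central range.

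Across the genome, 13266 named genes were counted. Of these, 2589 (19.5%) were at least 2-fold higher with CTCF shRNA and 1818 (13.7%) at least 2-fold lower. At least 4-fold differences were found for 490 higher and 441 lower genes, and at least 8-fold differences for 63 higher and 125 lower genes. The direction went with signal strength. Among the 4422 genes of lowest mean signal, 1604 were higher and 421 lower, whereas among the 4422 genes of highest mean signal 363 were higher and 679 lower. A total of 1060 genes were seen on the CTCF shRNA array only and 672 on the non-targeting array only. Among genes seen on both arrays the counts were nearly equal, at 1641 higher and 1660 lower. For 53.5% of the higher genes and 13.8% of the lower genes, the signal did not exceed that of the brightest control probe on the CTCF shRNA array. After normexp background correction with quantile normalization, 1056 genes were higher and 1172 lower. Of 127 genes chosen for naming that differed at least 2-fold, 38 fell below 2-fold there, among them AFP, AKR1B10, BMP4, CD2, CD3E, CD36, CDKN2B, DLX5, EPCAM, IFIT2, IRF1, MMP7, MMP14, OAS1, RPL3, RPS2, SDHD, SP5, SPANXA1 and TNF. Probes printed 10 times had a median SD of 0.10 for the log2 difference between their spots, which is noise within the arrays and does not measure variation between cultures. Pearson's r of the normalized signals was 0.93 across the 11491 genes seen on both arrays, which are not independent replicates. Over 3523 genes with several probes seen on both arrays, the probes shared a sign in 71.1%, and r between the 2 brightest probes was 0.66. Among the 848 of these at least 2-fold apart, the probes shared a sign in 84.7%, or in 91.5% of the higher and 79.0% of the lower genes.

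**Figure D1:**
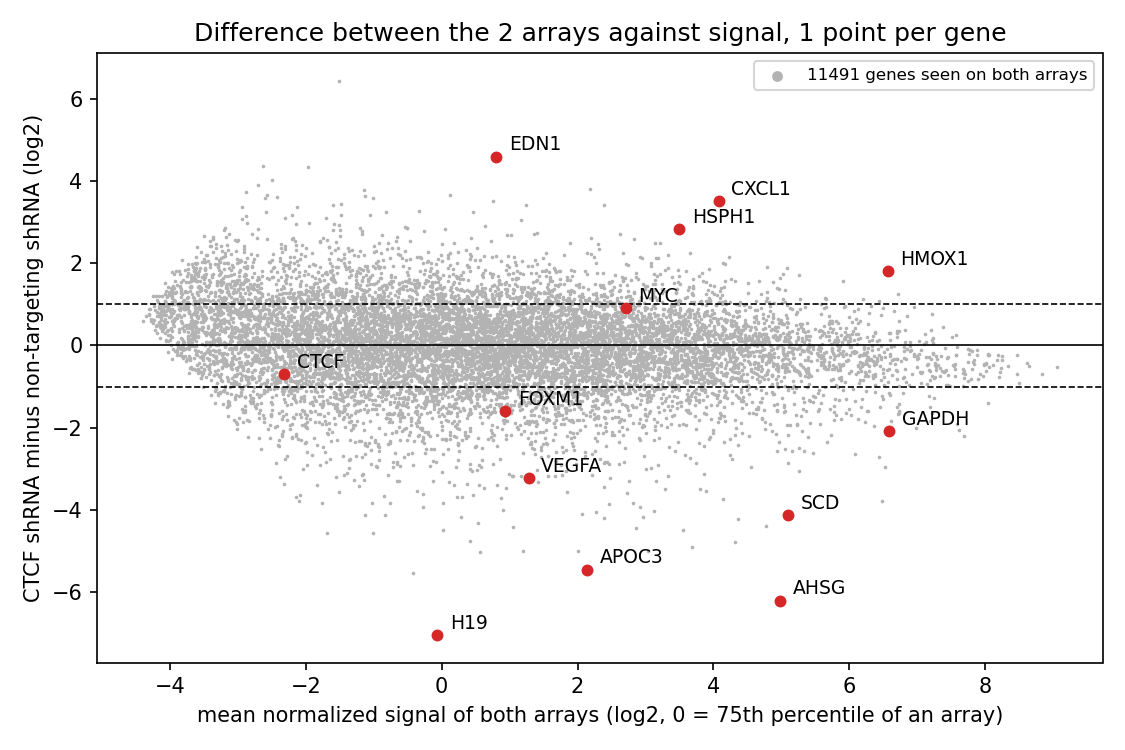
Log2 difference between the CTCF shRNA array and the non-targeting array (y axis) against the mean normalized log2 signal of both arrays (x axis), 1 grey point for each of the 11491 genes seen on both, with named genes in red and dashed lines at 2-fold. Points at low signal lie mostly above 0, and H19 (-7.03), AHSG (-6.20) and APOC3 (-5.45) lie lowest among the labelled genes.

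Genes of hepatocyte function were lower with CTCF shRNA. Of 29 counted, 15 were at least 2-fold lower and 1 was higher, with a median of -1.21, below all 10000 random lists matched on mean signal, whose central 95% ran from -0.48 to 0.21. AHSG, the secreted glycoprotein fetuin-A, read 72493 units in the control and 1387 with CTCF shRNA. APOC3, an apolipoprotein of triglyceride-rich particles, was lower by 5.45 on the log2 scale. The gluconeogenic enzyme gene PCK1 was 27.2-fold lower and G6PC1, seen on the non-targeting array only, at least 29.5-fold lower. After normexp and quantile normalization they differed by -4.24 and -3.29. CEBPA differed by -4.18 and ALB, the albumin gene, by -2.71. Not all liver transcripts shared the difference, since TTR differed by 0.22, FGG by 0.21 and FGA by -0.02. The 1 higher gene, CYP2E1, was seen on the CTCF shRNA array only.

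Hypoxia and glycolysis genes were lower to a similar degree. Of 24 counted, 15 were at least 2-fold lower and 1 higher, with a median of -1.32 against -0.52 to 0.25 for random lists. ANKRD37 was 9.40-fold lower, the aldolase gene ALDOC 7.04-fold lower and DDIT4, an inhibitor of mTORC1 signalling, 6.26-fold lower. VEGFA was 9.39-fold lower by its main probe (SD 0.10 over 9 spots), while its other 3 probes ranged from -1.29 to 0.41. ALDOA was higher, by 1.24. Genes of the unfolded protein and amino acid stress responses, a list that shares VEGFA and DDIT4 with the hypoxia list, had a median of -0.79 over 25 genes (percentile 0.04), with 8 at least 2-fold lower and 0 higher. TRIB3 was 3.85-fold lower and the protein disulfide isomerase gene PDIA4 3.78-fold lower, while HSPA5 differed by -0.77. Fatty acid and lipid genes had a median of -0.85 over 23 genes (percentile 0.02), with 10 lower and 3 higher. FABP1, the liver fatty acid binding protein, was 20.8-fold lower and the desaturase gene SCD 17.3-fold lower, by -2.47 and -1.68 at its other 2 probes. PLIN2, a lipid droplet coat protein, was 5.08-fold lower, whereas CD36 was 4.66-fold higher at a signal below the brightest control probe.

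Ribosomal protein genes had a median of -0.57 over 34 genes, at percentile 1.23, with 5 at least 2-fold lower and 0 higher. RPLP0 was 3.76-fold lower and RPL3 2.81-fold lower, and their other probes were lower too. RPS2 was 2.64-fold and RPS9 2.54-fold lower. This list lay inside the central range after cyclic loess, at -0.17 and percentile 3.5. Scaling on the reference genes, which adds 0.57 to the differences of genes seen on both arrays, brought its median close to 0. RPLP0 belongs to both the ribosomal and the reference list, so these lists overlap. The reference genes had a median of -0.58 over 16 genes, at percentile 2.78, just inside the central range, and at percentile 0.70 after cyclic loess. GAPDH was 4.24-fold lower (SD 0.09 over 7 spots), the transferrin receptor gene TFRC was 2.90-fold lower and the glycolytic gene PGK1 differed by -1.59, and these stayed lower under each scaling. Genes of the mitochondrial respiratory chain had a median of -0.39 over 31 genes (percentile 13.7), and SDHD, at -1.04, was the 1 gene past 2-fold. UQCRC1 differed by -0.91 and NDUFB5 by -0.93. Cholesterol synthesis genes had a median of -0.40 over 19 genes (percentile 10.7), with 5 lower and 1 higher. SREBF2, a transcription factor of this pathway, differed by -2.17 and the enzyme genes MSMO1 and DHCR7 were 3.29-fold and 3.24-fold lower.

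The list of targets of NRF2 and of xenobiotic receptors was higher as a group with CTCF shRNA. Of 18 counted, 10 were at least 2-fold higher and 0 lower, with a median of 1.19, above all random lists, whose central 95% ran from -0.49 to 0.46. HMOX1, which degrades heme, was 3.48-fold higher (SD 0.07 over 9 spots) and read 66731 units with CTCF shRNA. SRXN1, which repairs oxidised peroxiredoxins, was 4.35-fold higher and OSGIN1 3.47-fold higher. AKR1B10 was at least 3.46-fold higher but dimmer than the brightest control probe. NQO1, CYP1A1 and ABCC2 differed by 0.22, -0.06 and -0.18. After normexp and quantile normalization the list median was 0.53, at percentile 99.3. Heat shock genes had a median of 0.93 over 14 genes, above all random lists, with 6 higher and 1 lower. The chaperone genes HSPH1, HSP90AA1 and DNAJA1 were 7.11-fold, 4.45-fold and 4.04-fold higher, and the other 3 probes of HSP90AA1 differed by 1.84 to 3.01. CRYAB, a small heat shock protein gene, was 4.04-fold lower. Cancer-testis genes, which are mostly silent outside the germline and tumours, had a median of 1.07 over 16 genes (percentile 99.96), with 9 higher and 0 lower. CTAG2 was 2.67-fold higher, and SPANXA1 was 2.78-fold higher at a signal below the brightest control probe. Several genes of this list have near-identical paralogs that the probes may not separate, and the 12 members brighter than the control probes on at least 1 array had a median of 0.82, with 5 higher.

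**Figure D2:**
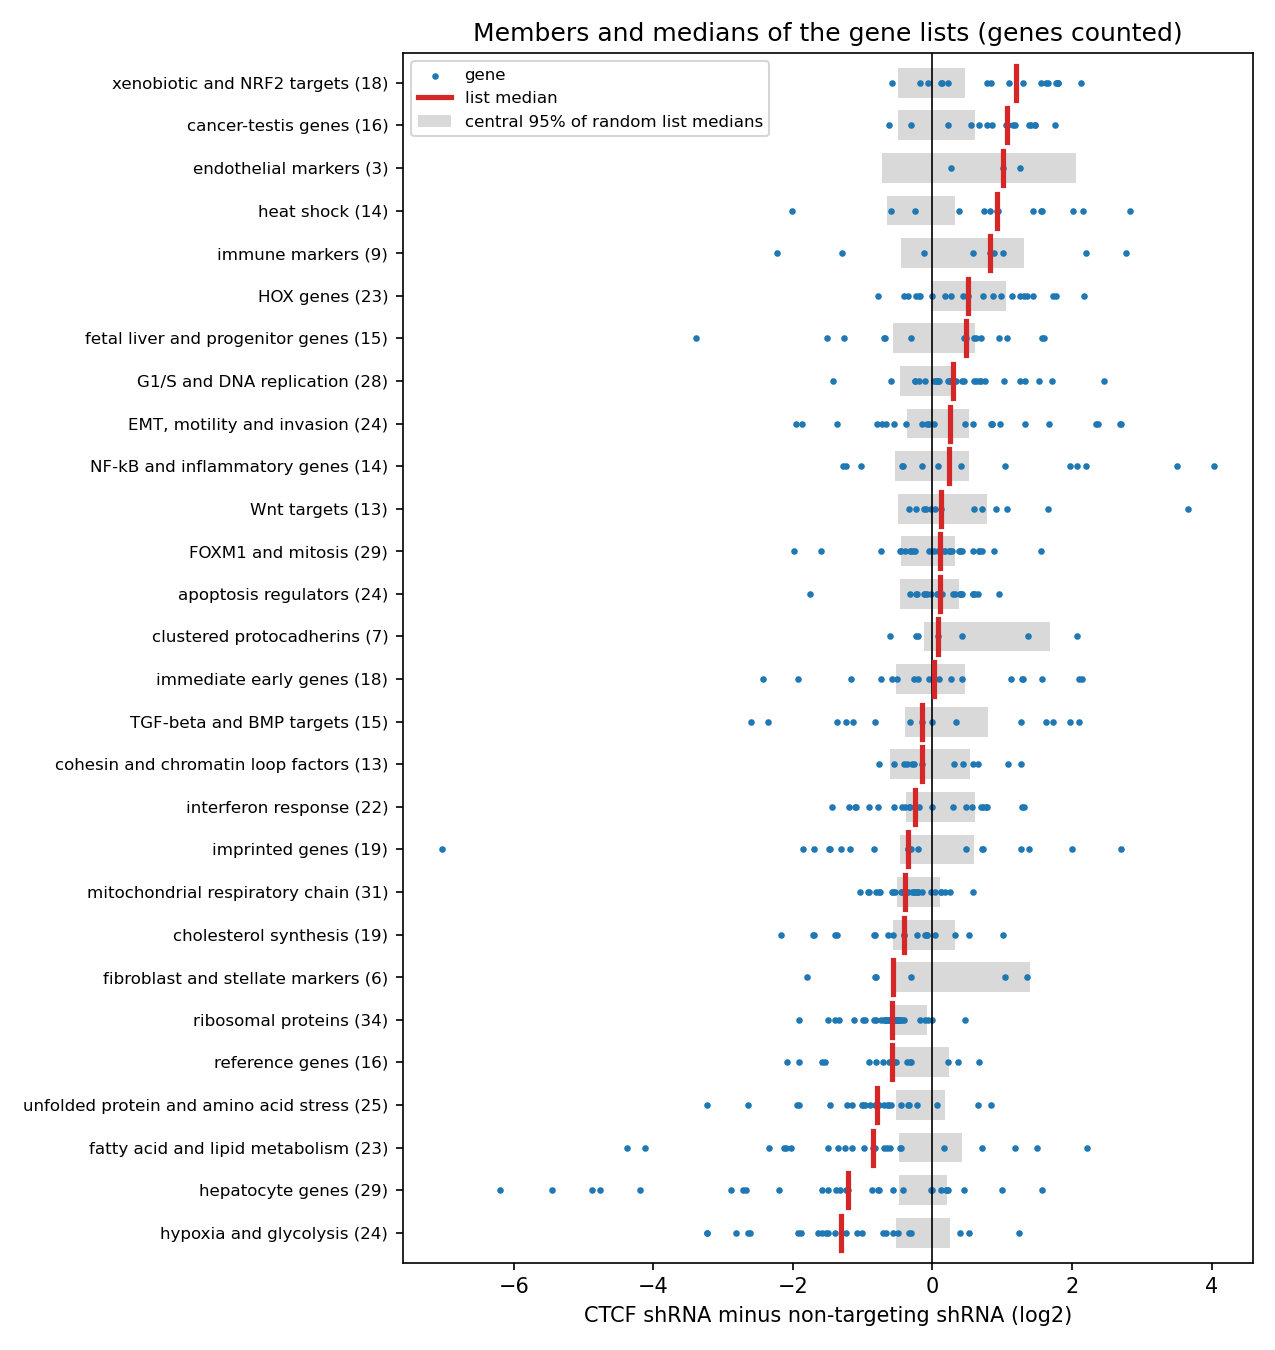
Log2 differences between the CTCF shRNA and non-targeting arrays (x axis) of the members (blue points) of 28 gene lists (y axis, genes counted in parentheses), with list medians in red and the central 95% of 10000 matched random list medians as grey bars; another scaling moves the points of genes seen on both arrays alike, and bounds not always. The hypoxia and hepatocyte medians (-1.32 and -1.21) lie left of their bars and the NRF2 median (1.19) lies right of its bar.

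Medians are shown for 28 lists, of which 3 lay above and 5 below the central 95% of random lists. After normexp and quantile normalization the counts of genes at least 2-fold higher and lower were 4 and 0 for the cancer-testis list, 7 and 0 for NRF2, 1 and 8 for lipid genes, 0 and 2 for ribosomal proteins, 2 and 6 for imprinted genes, 3 and 2 for inflammatory genes, 1 and 2 for immediate early genes, 0 and 2 for fetal liver genes, 0 and 1 for immune markers and 0 and 0 for protocadherins. The FOXM1 and mitosis list was not among those outside the range. Its median was 0.11 over 29 genes (percentile 81.3), with 1 gene higher and 2 lower. FOXM1 read 891 units in the control and 415 with CTCF shRNA (log2 difference -1.59, scanner error 0.20), and the cyclin gene CCNB2 was 3.94-fold lower. CENPF, a kinetochore protein gene, was 2.93-fold higher and the spindle checkpoint gene BUB1B differed by 0.89. Genes of the G1/S transition and DNA replication had a median of 0.30 over 28 genes (percentile 97.0), with 6 higher and 1 lower. The phosphatase gene CDC25A was 5.50-fold higher, MCM10 3.27-fold and the cyclin gene CCNE1 2.87-fold. E2F2 was 2.67-fold lower at its main probe and differed by 0.13 at the other. Of cell cycle inhibitors, CDKN1A (p21) was 2.62-fold lower (SD 0.20 over 8 spots) and CDKN2B (p15) 2.66-fold higher. Apoptosis regulators had a median of 0.11 over 24 genes (percentile 75.2), and BMF, at 3.38-fold lower, was the 1 gene past 2-fold. BBC3 differed by 0.95 at its main probe and by -1.59 and -0.87 at the other probes. CASP8 differed by 0.65 at its main probe and by -0.29 at the other, and PMAIP1 by 0.61.

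Signalling genes went both ways. Inflammatory genes had a median of 0.24 over 14 genes (percentile 85.0), with 6 higher and 3 lower, but of -0.037 over the 12 seen on both arrays (percentile 61.2). The neutrophil chemokine genes CXCL3, CXCL1 and CXCL2 were 16.4-fold, 11.3-fold and 4.60-fold higher. CXCL3 read 11.7 units in the control and differed by 1.91 after normexp and quantile normalization, and CXCL1 read 21479 units with CTCF shRNA. CCL20, SOD2 and NFKBIA differed by -1.28, -1.24 and -1.02. TNF was at least 4.20-fold higher, at a signal below the brightest control probe. Interferon response genes had a median of -0.25 over 22 genes (percentile 7.25), with 2 higher and 4 lower, and with 0 and 0 after normexp and quantile normalization. OAS1 and IRF1 were 2.70-fold and 2.30-fold lower and IFIT2 was 2.44-fold higher, all at signals below the brightest control probe. Immediate early genes had a median of 0.02 over 18 genes (percentile 55.7), with 6 higher and 3 lower, and with 1 and 2 after normexp and quantile normalization. The median was -0.055 over the 17 seen on both arrays and -0.23 over the 14 brighter than the brightest control probe. ZFP36 and DUSP1 were 5.40-fold and 3.79-fold lower, and DUSP6, a phosphatase that acts on ERK, was 4.42-fold higher. Wnt targets had a median of 0.12 over 13 genes (percentile 55.4), with 3 higher and 0 lower. The Wnt antagonist gene DKK1 was 12.6-fold higher and SP5 was 2.10-fold higher. Targets of TGF-beta and BMP had a median of -0.15 over 15 genes (percentile 14.4), with 5 in each direction, and with 0 higher and 4 lower after normexp and quantile normalization. ID2 was 5.11-fold lower and the activin subunit gene INHBE 6.03-fold lower, whereas BMP4 was 3.90-fold higher but differed by 0.47 after that normalization.

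Genes of epithelial-mesenchymal transition and invasion had a median of 0.25 over 24 genes (percentile 78.3), with 6 higher and 3 lower, but of -0.013 over the 22 seen on both arrays (percentile 35.8) and -0.15 over the 17 brighter than the brightest control probe, with 2 higher and 3 lower. The matricellular genes CCN2 and CCN1 were 6.48-fold and 5.07-fold higher, and the other 2 probes of CCN1 differed by 2.09 and 2.49. The matrix metalloproteinase gene MMP7 was 5.16-fold higher and MMP14 at least 6.47-fold higher, both at signals below the brightest control probe. FN1 and ITGA5 differed by -1.87 and -1.95. Fetal liver and progenitor genes had a median of 0.48 over 15 genes (percentile 93.3), with 3 in each direction, but of -0.31 over the 11 brighter than the brightest control probe (percentile 21.8), with 1 higher and 3 lower. The aminopeptidase gene ANPEP was 10.4-fold lower and GPC3, a proteoglycan raised in liver cancer, 2.85-fold lower. AFP and EPCAM were 3.02-fold and 2.96-fold higher, both below the brightest control signal. HOX genes had a median of 0.51 over 23 genes (percentile 58.6), with 8 higher. Only 1 was higher among the 12 seen on both arrays and 1 after normexp and quantile normalization, and HOXB4 was 3.40-fold higher. Clustered protocadherins, of which 7 were counted, had a median of 0.09 (percentile 17.6), and none was brighter than the brightest control probe. Markers of other cell types were few. Fibroblast and stellate markers had a median of -0.56 over 6 genes (percentile 2.80) and immune markers 0.82 over 9 genes (percentile 81.5). The immune median was 0.23 over the 6 seen on both arrays, with 0 higher and 2 lower, -0.010 after normexp and quantile normalization and -1.30 over the 3 brighter than the brightest control probe. Of 3 endothelial markers counted, 2 were seen on the CTCF shRNA array only, and their median of 1.02 (percentile 60.2) fell to 0.020 after normexp and quantile normalization. CD68, a lysosomal protein of macrophages, was 4.68-fold lower, and CD2 and CD3E of T cells were at least 6.81-fold and 4.59-fold higher at signals below the brightest control probe.

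The largest differences measured on both arrays included genes outside these lists. Higher genes included KRTAP3-1, a hair keratin-associated protein gene, at 86.5-fold, and EDN1, the endothelin-1 gene, at 24.1-fold (SD 0.15 over 8 spots). After normexp and quantile normalization they differed by 3.87 and 4.01. ZSCAN18, UCP3, SDR42E1, NFASC, ZNF107, ARHGDIB and LCMT2 were between 12.4-fold and 20.6-fold higher from control signals of 9.53 to 34.8 units, and differed by 1.56 to 2.54 after that normalization. The second probes of ZNF107 and UCP3 differed by -0.12 and 1.59. PPP1R10, a nuclear regulator of protein phosphatase 1, was 13.9-fold higher and went from 326 to 6354 units. Lower genes included LOX, the collagen crosslinking enzyme lysyl oxidase, at 46.5-fold (SD 0.26 over 10 spots), and the receptor tyrosine kinase gene AXL at 32.1-fold. TMEM37, NEB and ATP8B3 were 32.3-fold, 31.7-fold and 23.4-fold lower. LHPP was 31.8-fold lower at its main probe and differed by -1.03 at the other. MST1, the hepatocyte-derived macrophage stimulating protein gene, was 29.8-fold lower, as was its near-identical copy MST1P2, at 27.4-fold, which the probes may not tell apart. ANGPTL8, a liver-secreted regulator of lipoprotein lipase, was seen on the non-targeting array only. It was 210-fold lower as measured, with a scanner error of 0.37 on the log2 scale. The liver pyruvate kinase gene PKLR and the arginase gene ARG1 were at least 34.6-fold and 28.8-fold lower. CAPN12, also seen on the non-targeting array only, was 24.8-fold lower as measured. After normexp and quantile normalization ANGPTL8, PKLR, ARG1 and CAPN12 differed by -5.68, -3.25, -3.12 and -2.69. A second probe of PKLR, left out as non-uniform, differed by 0.31. On the CTCF shRNA array only, the beta-globin gene HBB was at least 87.7-fold higher with an SD of 0.57 over 8 spots. ITLN2, H2AP, LINC00311 and NOVA2 were at least 14.1-fold, 13.2-fold, 12.7-fold and 11.8-fold higher. After normexp and quantile normalization they differed by only 1.30, 1.56, 1.18 and 1.38, and HBB by 3.97, so the bounds hold for the main scaling alone.

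The E1A and eQC control probes, which match no human transcript, read higher on the CTCF shRNA array. Of 14 such probes, 12 exceeded the 95th percentile of the negative controls on that array, up to 131 units for the brightest. The negative control probes had a median processed signal of 4.71 units there and 1.98 on the non-targeting array, close to the medians of its error (4.68 and 1.97), and raw medians of 37 and 34 units. The labels do not say whether RNA for these probes was added to the sample, so a signal below the brightest control probe is a comparison of level and does not by itself mark background. Scaling on the median of all probes and on the reference genes moved the median log2 difference of all genes by -0.83 and 0.57, and with it the counts above.

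**Figure D3:**
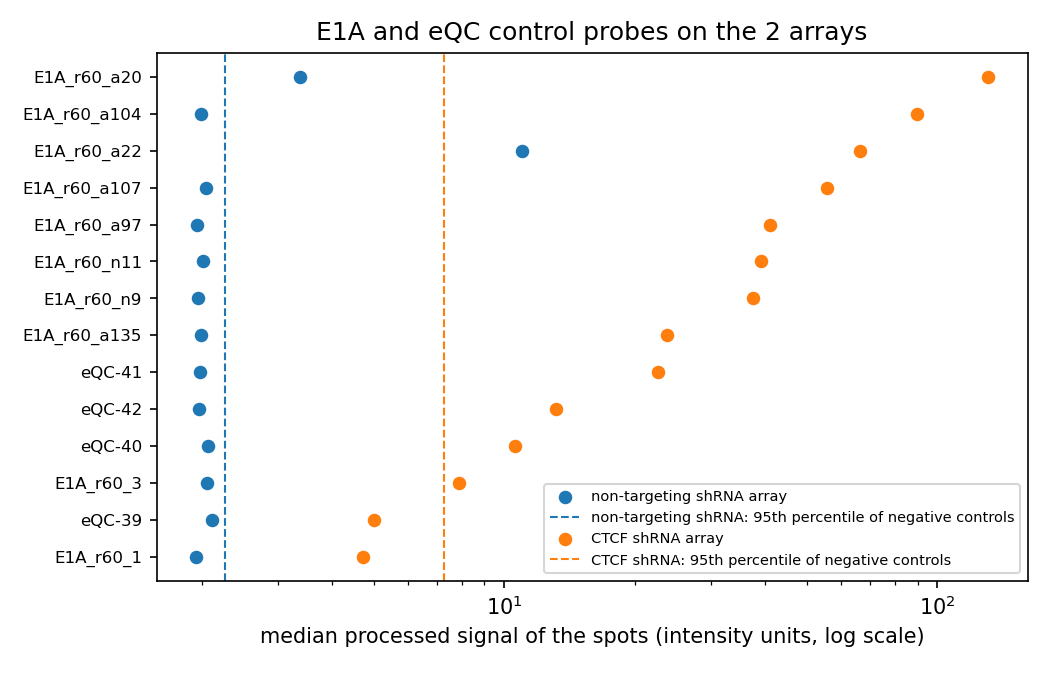
Median processed signal (x axis, intensity units, log scale) of 14 E1A and eQC control probes (y axis) on the non-targeting array (blue) and the CTCF shRNA array (orange), with dashed lines at the 95th percentile of the negative controls (2.26 and 7.26). All but 2 of these probes read above the line on the CTCF shRNA array, from 7.84 to 131 units.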

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

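The tests of the control probes, of the spots marked non-uniform and of another cell line were chosen after the values were seen. The tests by cyclic loess were chosen before their results were seen.

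Control probes that match no human transcript gave signal above the 95th percentile of the negative controls on the CTCF shRNA array. The E1A probes read 130.9 (a20), 89.52 (a104), 66.16 (a22), 55.56 (a107), 41.15 (a97), 39.2 (n11), 37.51 (n9), 23.73 (a135) and 7.844 (E1A_r60_3) intensity units there. The eQC probes 41, 42 and 40 read 22.59, 13.16 and 10.61 units. On the non-targeting array a22 read 10.98 units, a20 read 3.37 and the others read at most 2.11.

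The excess of higher over lower genes lay among dim genes, with 79.2% of the at least 2-fold differences in the third of genes of lowest signal being higher with CTCF shRNA. Spots marked non-uniform do not account for it, since that share was taken after they were left out, although they had a median log2 difference of 1.70. Uneven signal in spots that were not marked was not tested. Non-specific signal on the CTCF shRNA array is a candidate explanation, as the control probes were higher by a median log2 difference of 3.05. Most of them read near the negative controls' median of 1.98 units on the non-targeting array, so that size is not exact. RNA added to the CTCF shRNA sample could instead raise the control probes alone, which was not tested. The control probes rose unevenly on that array. E1A_r60_1 read 4.71 units, with 0 of 32 spots well above background, against 131 units for a20. A lower CTCF level in the cells stays open as an untested biological explanation, and 1 array per group leaves it confounded with the array. Bounds such as those of HBB, ITLN2 and NOVA2 on the CTCF shRNA array alone therefore need a second measurement.

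The hepatocyte list and the hypoxia and glycolysis list were lower with CTCF shRNA by medians of -1.21 and -1.32. A weaker readout of bright probes on that array, alike for genes of like signal, is argued against. Both lists lay at percentile 0 and 0 of lists matched on mean signal. The matching already sets such a trend aside, so the same percentiles after cyclic loess, which removes a trend with signal, add little. RNA of another cell line could lower liver genes too, and lines that differ in karyotype shift long stretches of neighbouring genes. Of windows of 41 neighbouring genes, 10.1% exceeded the 95th percentile of shuffled orders, between the bounds set for and against that source, so with 1 array per group that source cannot be told apart from the knockdown. The knockdown, cell density and oxygen supply of the cultures stay open, untested.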

How the results depend on the processing

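No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out. Genes brighter than the brightest control probe, measured values in place of bounds and leaving out genes whose probes disagree were chosen after seeing the data. The main values are 2589 higher and 1818 lower genes (58.7% higher), -0.70 for CTCF and 0.054 for the FOXM1 and mitosis list relative to all genes. Normexp with quantile normalization gave 1056 higher and 1172 lower genes (47.4% higher) and -0.48 for CTCF. It adds an offset that shrinks differences of dim genes, and of 127 genes chosen for naming that differed at least 2-fold 38 fell below 2-fold, with 0 of opposite sign. There the invasion, immune, protocadherin and cohesin medians changed sign, to -0.026, -0.010, -0.23 and 0.011, all inside the central range. Scaling on the median of all probes gave 600 higher and 5445 lower (9.93% higher) and -1.58 for CTCF, and it moved the median of all genes by -0.83. Scaling on the reference genes gave 4806 and 835 (85.2% higher) and -0.13, with a shift of 0.57. Scaling on probes seen on both arrays gave -0.55 for CTCF, with a shift of 0.15. These shifts come from the scaling itself. Over 12 alternatives that measured it, CTCF lay between -1.58 and -0.13. The value of -0.13 lies within the scanner error of 0.24, and 5 of the alternatives leave the value of CTCF as it was by construction. Cyclic loess gave -1.09 for CTCF, 0.17 for the mitosis list and 44.1% higher. Without a filter on dim probes 3897 genes were higher (64.6%) and the mitosis list lay at -0.19 relative to all genes. The list's own median stayed at 0.11, while the median of all genes rose from 0.059 to 0.30. Among genes seen on both arrays 1641 were higher (49.7%), from fewer genes. Among genes brighter than the brightest control probe 1203 were higher (43.4%) and the mitosis list lay at 0.19 relative to all genes. The list's own median was 0.14 there and that of all genes -0.055, and CTCF itself was too dim to enter. Keeping spots marked as outliers gave 67.0% higher and -0.052 for the mitosis list relative to all genes. The list's own median was 0.12 there and that of all genes 0.17. PKLR turned to 0.31, as another of its probes became the brightest. At 1.5-fold 4111 genes were higher and 3183 lower, and at 3-fold 1029 and 815. Where no construction is named, the cause was not tested. The hepatocyte, hypoxia, stress, lipid, heat shock, NRF2 and cancer-testis lists stayed outside the central 95% of matched lists in all 9 settings with percentiles. The ribosomal list did not after cyclic loess, at percentile 3.5. Lists inside the range in the main setting left it in some. The reference genes lay below it in 6 of 8 alternatives, at percentiles from 0.70 to 2.35. With the median over a gene's probes the cholesterol, fibroblast and interferon lists lay below it, at 1.3, 2.25 and 2.3, and with outlier spots kept the cholesterol and fibroblast lists did, at 1.65 and 1.45. The imprinted list lay at 0.60 after cyclic loess and at 0.10 among genes brighter than the controls, and without a filter the G1/S and inflammatory lists lay above the range, at 98.2 and 97.8. Signal over background limits CTCF itself, the protocadherins and most HOX genes, which lay near the level of the control probes.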

Other observations

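The tests in this part were chosen after the differences were seen. Gene families were formed from 91 shared starts of gene symbols with at least 15 counted genes, histones included, and each median was placed among 2000 random lists matched on mean signal.

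Zinc finger genes of the ZNF family were higher with CTCF shRNA, with 162 of 363 at least 2-fold higher, 10 lower and a median of 0.89 against 0.00 to 0.28 for random lists. ZNF256, ZNF45 and ZNF112 differed by 3.24, 2.92 and 2.86, and ZNF395 by -2.34. RNA helicase genes were higher too, with a median of 0.84 over 32 DDX genes, 10 of them at least 2-fold higher and 0 lower. DDX28, DDX51 and DDX49 differed by 2.22, 1.80 and 1.76. Mitochondrial ribosomal protein genes (MRPL, 51 genes) had a median of 0.31, above the random range of -0.40 to 0.13, whereas cytosolic ribosomal protein genes were lower (RPL, 59 genes, median -0.50, pseudogenes included). Subunits of RNA polymerases (POLR, 32 genes) had a median of 0.56 and WD repeat genes (WDR, 47 genes) 0.49. The families named are not the only ones outside their random ranges. ZSCAN, KLHL and DHX genes lay above theirs (medians 1.08, 0.85 and 0.77), and HLA and ATG genes below (-0.44 and -0.60). With 91 families, some would lie outside such a range by chance. These directions are relative to genes of like signal, since scaling on the median of all probes moves the median of all genes by -0.83.

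Histone genes had a median of -0.44 over 71 genes, below the random range of -0.24 to 0.31, with 23 at least 2-fold lower and 7 higher. H2BC13, H1-4, H2BC14 and H2BC12 differed by -2.29, -2.06, -2.02 and -1.82, and H3C1 by 2.53. Clustered histone genes are close in sequence, and whether their probes measure them separately was not tested. The 56 histone genes brighter than the brightest control probe on at least 1 array had a median of -0.67. Solute carriers (SLC, 254 genes) had a median of -0.20 against 0.00 to 0.25 for random lists, and transmembrane genes (TMEM, 166 genes) -0.26 against -0.13 to 0.20. Tetraspanins (TSPAN, 17 genes) had a median of -0.83. These directions too are relative to genes of like signal, since scaling on the reference genes moves the median of all genes by 0.57.

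Non-specific signal could raise ZNF genes, many of which are dim. The 167 ZNF genes above the level of the brightest control probe on the non-targeting array had a median of 0.57, against -0.18 to 0.17 for lists matched on that array's signal. Were each of these genes to carry the whole signal of that control probe, their median without it would be 0.055, at percentile 73.85 of those lists with their signal kept, so non-specific signal of that size on ZNF probes alone cannot be told apart from a higher level with 1 array per group. The 196 dimmer ones had a median of 1.15 and lie at or under the level of that probe, so they do not decide it. Related sequences within this family, which 1 set of transcripts could light up at many probes, were not tested, and a shared response of ZNF genes to the CTCF shRNA stays open as a hypothesis.

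Since CTCF bounds chromatin domains, neighbouring genes could differ together after its knockdown. Over 10862 adjacent pairs, with pairs of 1 name family left out, the differences correlated with r = 0.055, above the range of -0.019 to 0.019 of 2000 shuffled orders. The trend with mean signal had been removed first. The correlation is across genes, which are not independent replicates, and no comparison without CTCF knockdown was made, so shared regulation of neighbours for other reasons may give the same value. The largest chromosome median was 0.19 in absolute size over 23 chromosomes.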
